A study of Mus musculus with 13 samples.

How the data were processed

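RNA from whole hearts of 13 male C57Bl6 mice was sequenced. Per the labels, surgery took place at 12 weeks of age and the hearts were taken at 17 weeks. The 4 groups were formed from the sample titles: Sham (3 hearts, sham surgery, no injection), IR (3 hearts, ischaemia and reperfusion, no injection), IR virus (3 hearts, IR and a control virus) and IR edit (4 hearts, IR and a functional editing system for CaMKIIδ). CaMKIIδ is a calcium/calmodulin-dependent kinase of heart muscle, and base editing changes single bases of a gene. The labels give no batch, sequencing date or time of day of harvest, and give no dose or kind of virus.

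The deposited files hold raw read counts per gene symbol, 1 file per library, for 53278 symbols. Their values are whole numbers whose totals differ between libraries. Per the submitters' processing notes the tools were FastQC 0.11.8, Trimmomatic 0.39, HISAT2 2.1.0 and featureCounts 1.6.2, with genome build mm10. The gene annotation behind the counts and the strandedness of counting are not given in the sources used here. Symbols were looked up in the GENCODE mouse release M21 for positions and gene types: 49721 of the 53278 symbols (93.3%) were found, and 15389 of the 15690 genes tested. A few genes share reads with near-identical copies, which makes their counts uncertain.

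Counts were analysed in R 4.3.3. Libraries were scaled with TMM and genes with low counts removed with filterByExpr in edgeR 4.0.16, which left 15690 genes. A model with a mean per group was fitted to all 13 libraries with edgeR's quasi-likelihood test and a Benjamini-Hochberg adjustment over all genes tested, with an adjusted p of 0.05 as the threshold. The fit had 9 residual degrees of freedom, 6.08 prior degrees of freedom and a common biological coefficient of variation of 0.116. Log2 fold changes carry a standard error (SE) derived as the absolute log2 fold change divided by the square root of the test's F statistic. Levels are CPM values, counts scaled to a common library size with TMM, given as mean ± SD over hearts. The 6 comparisons were IR, IR virus and IR edit each against Sham, IR edit against IR virus, IR edit against IR, and IR virus against IR.

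The comparisons, the test, the rule for naming genes, the gene lists and the other settings to be tried were chosen before the data were examined. The rule named Camk2d in every comparison. In the 4 comparisons against Sham or between IR edit and IR virus, it also named the 6 genes with the largest positive and the 6 with the largest negative log2 fold change that passed the test, had a mean of at least 1 CPM and separated the groups completely. From each of the 6 lists with the smallest set-test p and at least 1 member called, it added the 3 members with the smallest p. Any other list was illustrated by its member with the smallest p. For IR edit against IR and IR virus against IR it took 5 genes per direction, or the 5 smallest p where nothing passed. Symbols without a gene name were passed over in favour of the next gene.

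The 35 gene lists covered heart muscle, matrix, vessel and blood cell types, energy metabolism, stress responses, the daily clock and tissues that a dissected heart could carry along. Of these, 34 had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with a Benjamini-Hochberg adjustment over the lists of a comparison. The same test with an estimated correlation is given beside the calls. Counts of members called over all genes tested stand beside counts adjusted over the list alone.

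A further measure asked whether the editing system moved genes against the injury change: the correlation across genes between IR minus Sham and IR edit minus IR virus, which share no library. Its p came from an exact two-sided permutation of the 7 IR edit and IR virus labels (35 splits). An IR score per heart was the mean log2 CPM (prior count 2) of the 100 genes with the smallest p among those higher in IR minus that of 100 lower in IR, chosen in a fit of the Sham and IR libraries alone. IR edit and IR virus scores were compared with the exact two-sided permutation test over the same 35 splits, whose smallest possible p is 0.029.

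The pipeline was tested on simulated data with 15486 tested genes. A planted 2-fold change was recovered for 76% of the genes in IR against Sham and 84% in IR edit against IR virus, and a 4-fold change for 94% and 92%. False calls made up 6.08% and 4.88% of the calls. The single-gene changes were planted outside the gene lists, genes were drawn independently and each gene had the same spread in every group. The shares recovered therefore need not hold for injury genes or for groups of unlike spread. Alternatives tried were DESeq2's size factors, no filter, a filter of 1 CPM in 3 libraries, a robust dispersion, the number in the title as a block, the Wald test of DESeq2 1.42.0, a fit of only the 2 groups compared, an estimated correlation for the lists, other gene numbers and scales for the score and the correlation, and leaving out each library in turn. A fit of the 9 libraries outside IR edit was added after the spread within IR edit had been seen. The numbers in the titles were checked as possible pairs: 3 of 18 pairs of like-numbered libraries correlated above 0.1 after group means were removed, and 6 of 13 libraries correlated best with one of their own number. The numbers were therefore not used as pairs. No library was left out.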

Results

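The data are gene-level read counts from 13 mouse hearts in 4 groups: Sham (n = 3), IR (n = 3), IR virus (n = 3) and IR edit (n = 4). IR stands for ischaemia and reperfusion, a temporary block of blood flow to heart muscle. Total counts per library ran from 20634820 (IR edit replicate 3) to 27265276 (Sham replicate 1). Transcripts of the mitochondrial genome took 36.3% ± 1.93 of the counts in Sham (SD, n = 3), 34.9% ± 0.666 in IR (n = 3), 33.2% ± 2.17 in IR virus (n = 3) and 32.8% ± 3.23 in IR edit (n = 4). The first principal component held 27.5% of the variance and the second 15.5%. On the first, IR edit replicates 1 to 4 lay at 10.2, 34, -2.8 and 45.1, and the other 9 hearts between -26.5 and 3.83.

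Camk2d, which encodes the kinase that the editing system targets, did not pass the test in any comparison. The gene lies on chromosome 3 of mm10 from 126596302 to 126846326 on the plus strand. Its level was 251 ± 45.1 CPM in Sham (SD, n = 3), 241 ± 5.42 in IR (n = 3), 217 ± 18.4 in IR virus (n = 3) and 223 ± 17.9 in IR edit (n = 4). Between IR edit and IR virus its log2 fold change was 0.04 ± 0.11 (SE), with an adjusted p of 0.896 from edgeR's quasi-likelihood test. The smallest adjusted p among the 6 comparisons was 0.369, for IR edit against Sham at a log2 fold change of -0.17. The direction between IR edit and IR virus turned without IR virus replicate 2 (-0.02) or IR edit replicate 3 (-0.01). In IR against Sham it turned without Sham replicate 2 (0.01) or 3 (0.02). The kinase family and its calcium/calmodulin partners, 17 genes, held 1 member that passed over all genes, in IR edit against Sham. It was Camk2b, another subunit of the kinase, which rose by 0.34 ± 0.092 (SE) on the log2 scale (adjusted p = 0.0354). In IR virus against Sham Camk2b had a log2 fold change of 0.39 ± 0.097 and did not pass over all genes (adjusted p = 0.137). It was the 1 member called adjusted over the list alone in each of these 2 comparisons, and between IR edit and IR virus its log2 fold change was -0.05 ± 0.09 (adjusted p = 0.842). Gene counts do not show whether the codons of Camk2d were edited.

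**Figure D1:**
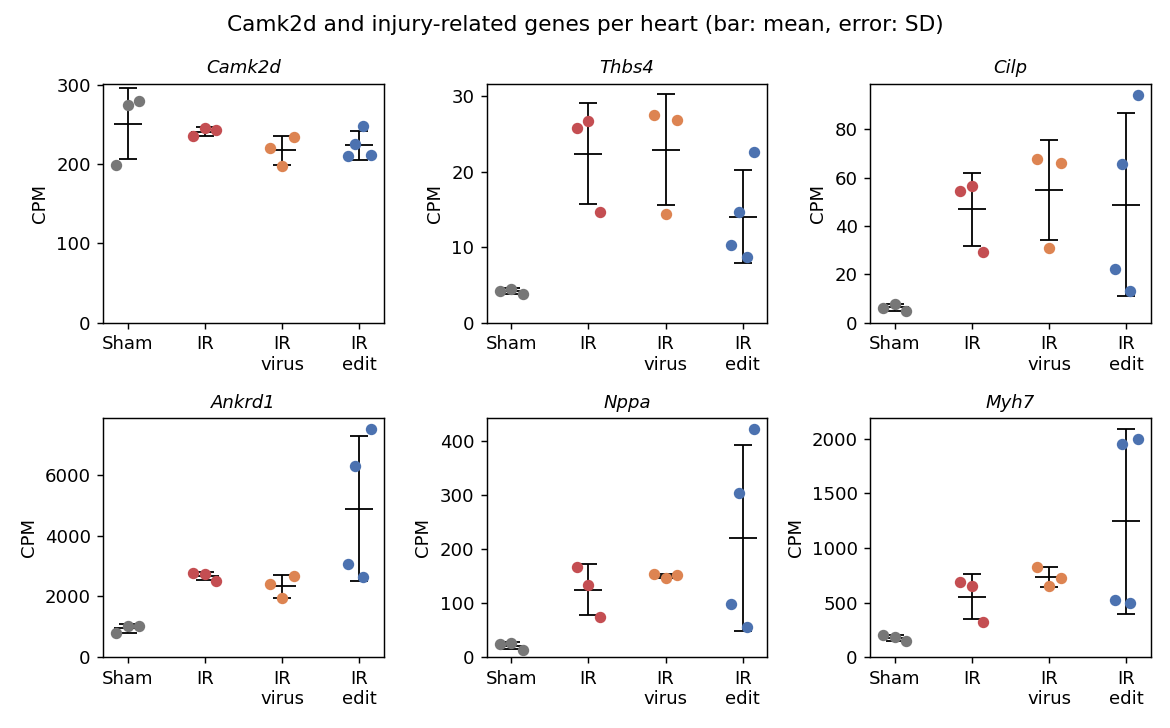
CPM of 6 genes on the vertical axes, with 1 point per heart in the 4 groups and the mean and SD as bars; Cilp, Nppa, Ankrd1 and Myh7 are drawn as well-known injury genes. Camk2d averaged 251 CPM in Sham and 223 in IR edit, while Thbs4 averaged 4.15 CPM in Sham and 22.4 in IR.

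The comparison of IR with Sham asks what the injury changed 5 weeks after surgery in hearts without injection. Thbs4, a matricellular protein of injured tissue, rose from 4.15 ± 0.377 CPM in Sham to 22.4 ± 6.69 in IR (SD, n = 3 each), a log2 fold change of 2.43 ± 0.35 (SE). Ano10, a member of the anoctamin membrane protein family, fell from 32.3 ± 0.669 to 20.8 ± 0.554 CPM, a log2 fold change of -0.64 ± 0.076. Among activated fibroblast and matricellular genes, all 43 tested members had a positive log2 fold change. Of these 1 passed over all genes and 28 adjusted over the list alone. Cilp and Sfrp2, secreted proteins of the matrix and of Wnt signalling, had log2 fold changes of 2.90 ± 0.59 and 2.55 ± 0.52 but did not pass over all genes (adjusted p = 0.188 for both). Collagens and their crosslinking enzymes had 28 of 29 members on the positive side, with 0 called by edgeR over all genes and 16 adjusted over the list alone. Col8a2, a short-chain collagen, had the smallest p (log2 fold change 2.14 ± 0.46, adjusted p = 0.191). Cardiac stress genes had 17 of 19 members on the positive side, 5 of them past the threshold adjusted over the list alone. Their member with the smallest p was Ankrd1, a stress-responsive protein of the sarcomere and nucleus, at 1.49 ± 0.30 (adjusted p = 0.188). These adjusted p come from the fit of all 13 libraries. With edgeR on the Sham and IR libraries alone, Cilp, Sfrp2, Col8a2 and Ankrd1 passed (adjusted p = 0.0012, 0.0152, 0.0244 and 0.000722).

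In edgeR's quasi-likelihood test, 2 of 15690 genes passed in IR against Sham: Thbs4 (adjusted p = 0.0345, higher in 3 of 3 hearts) and Ano10 (adjusted p = 0.00738, lower in 3 of 3). At an unadjusted p under 0.05 there were 1307 genes. The count was 48 with DESeq2, 115 in a fit of only the 2 groups, 156 in the fit of the 9 libraries outside IR edit, 598 without a filter and 1 with a robust dispersion. It was 0 without Sham replicate 2, IR replicate 1 or IR replicate 2, 1 without Sham replicate 3 and 5 without IR replicate 3. With a library left out, Thbs4 passed only without IR replicate 3 (largest adjusted p 0.262). Ano10 was lost without Sham replicate 2, IR replicate 1 or IR replicate 2 (largest adjusted p 0.12).

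Camera placed 15 of the 34 gene lists past the threshold in IR against Sham. The medians were 0.65 for activated fibroblast and matricellular genes (adjusted p = 8.53e-20), 0.59 for collagens (6.32e-13) and 0.56 for cardiac stress genes (4.83e-08), and they had adjusted p = 0.489, 0.489 and 0.499 with an estimated correlation. Immune lists on the positive side were MHC and antigen presentation (21 of 23 members positive, median 0.28, adjusted p = 2.82e-06), interferon-stimulated genes (28 of 30, median 0.20, 0.000341) and macrophage and monocyte genes (20 of 27, median 0.22, 0.000341). Each of these had adjusted p = 0.58 with an estimated correlation. Lymphatic endothelial genes (median 0.36, adjusted p = 0.00296) and B and plasma cell genes (median 0.68, 0.00142) both had adjusted p = 0.143 with an estimated correlation. Inflammatory cytokine and NF-kB genes (median 0.17, adjusted p = 0.00994) and atrial markers (median 0.40, 0.0119) had adjusted p = 0.499 and 0.58 with an estimated correlation. By edgeR over all genes 0 members of these 7 lists passed. Adjusted over the list alone, macrophage and monocyte genes had 5 higher and 1 lower, lymphatic endothelial genes 4 higher and 1 lower and atrial markers 2 higher. On the negative side, 51 of 52 nuclear-encoded respiratory chain genes (median -0.12, adjusted p = 2.73e-09) and all 13 mitochondrially encoded genes (-0.15, 0.00142) were lower in IR. So were 28 of 35 fatty acid genes (median -0.15, adjusted p = 8.09e-05), all 20 TCA cycle genes (-0.11, 0.000349) and all 8 red blood cell genes (-0.26, 0.0184). Those 5 lists had adjusted p = 0.58 with an estimated correlation, and none of their members passed in edgeR over all genes or adjusted over the list alone.

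The comparison of IR virus with Sham asks what the injury changed in hearts that also received the control virus. Thbs4 rose from 4.15 ± 0.377 CPM to 22.9 ± 7.38 (SD, n = 3 each), by 2.46 ± 0.35 (SE) on the log2 scale. Ano10 had a log2 fold change of -0.65 ± 0.076, from 32.3 ± 0.669 CPM to 20.6 ± 0.882. Activated fibroblast and matricellular genes had 41 of 43 members on the positive side, 1 called over all genes and 32 adjusted over the list alone. Cilp, at 3.13 ± 0.59 (adjusted p = 0.0781), and Sfrp2, at 2.69 ± 0.52 (adjusted p = 0.0846), did not pass over all genes. Collagens had 28 of 29 members positive and 21 called adjusted over the list alone, with 0 called by edgeR over all genes. Among cardiac stress genes 8 of 19 were called adjusted over the list alone. Nppa, the atrial natriuretic peptide, had their smallest p (2.83 ± 0.57, adjusted p = 0.0867).

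In edgeR's quasi-likelihood test 2 genes passed in IR virus against Sham, Thbs4 (adjusted p = 0.0288) and Ano10 (adjusted p = 0.00595), with 2411 genes at an unadjusted p under 0.05. Both passed in the same direction in IR against Sham. The count was 191 with DESeq2, 203 in a fit of only the 2 groups, 313 in the fit of the 9 libraries outside IR edit, 863 without a filter and 1 with a robust dispersion. It was 0 without IR virus replicate 3, 1 without Sham replicate 3 or IR virus replicate 1 and 7 without IR virus replicate 2. Thbs4 passed only without IR virus replicate 2 (largest adjusted p 0.282), and Ano10 was lost without IR virus replicate 3 (0.0518).

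Camera placed 15 lists past the threshold in IR virus against Sham. With an estimated correlation 0 passed, where the smallest adjusted p was 0.614 and 1 list had an unadjusted p under 0.05. Activated fibroblast and matricellular genes (median 0.82, adjusted p = 1.53e-16), collagens (0.80, 1e-12) and cardiac stress genes (0.56, 4.8e-07) had adjusted p = 0.614 with an estimated correlation. Immune lists on the positive side were MHC and antigen presentation (median 0.29), interferon-stimulated (0.17), macrophage and monocyte (0.24) and inflammatory cytokine and NF-kB genes (0.21). Atrial markers (median 0.59), proliferation (0.40), lymphatic endothelial (0.51) and adipocyte genes (0.68) were on that side too, and these 8 lists had adjusted p from 3.76e-05 to 0.0414. None of their members passed by edgeR over all genes. The calls adjusted over the list alone were 3 higher and 1 lower for macrophage and monocyte, 4 higher and 1 lower for lymphatic endothelial, 2 higher each for atrial and adipocyte and 1 higher for interferon-stimulated genes. Respiratory chain (median -0.11), mitochondrially encoded (-0.23), fatty acid (-0.14) and TCA cycle genes (-0.18) were on the negative side, with adjusted p from 7.5e-06 to 0.00235. With an estimated correlation these lists had adjusted p = 0.614, 0.665 or 0.693.

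The changes in IR and in IR virus against the same Sham hearts correlated across genes at r = 0.771. Simulated data with shared controls and no changed gene gave a mean r of 0.509, and genes are not independent replicates. The covariance was 0.0921 against 0.0295 in the simulations. With 3 Sham hearts the controls could not be divided with at least 2 in each part, so a share of the excess may stem from them.

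The comparison of IR edit with Sham asks what differed from uninjured hearts after the editing system was injected. Nr4a1, a nuclear receptor induced within minutes of many stimuli, rose from 3.04 ± 0.151 CPM in Sham (SD, n = 3) to 36.7 ± 12.3 in IR edit (n = 4), a log2 fold change of 3.59 ± 0.27 (SE). Nppa rose from 21.1 ± 6.97 to 220 ± 173 CPM (3.38 ± 0.57), with IR edit hearts at 98.9, 304, 55.9 and 422 CPM. Dio2, the deiodinase that activates thyroid hormone, rose by 3.43 ± 0.71, and Lrp8, a receptor of the LDL receptor family, by 3.31 ± 0.62. The IR edit replicates 1 to 4 were at 4.97, 27.0, 5.18 and 42.1 CPM for Dio2 and 2.12, 5.96, 1.09 and 8.78 for Lrp8. Mylk2, a myosin light chain kinase of skeletal muscle, and Syndig1, a membrane protein of synapses, rose by 4.75 ± 0.65 and 4.72 ± 0.65, from Sham counts of only 4, 2 and 1 reads and 3, 0 and 4 reads. Dbp, a transcription factor driven by the daily clock, was lower (-2.33 ± 0.18, from 29.7 ± 4.99 to 5.94 ± 1.72 CPM), and so were the clock repressors Per2 (-2.03 ± 0.35) and Per3 (-1.81 ± 0.20). Ccl11, the chemokine eotaxin (-1.96 ± 0.46), Rp1, a microtubule-associated protein (-1.91 ± 0.28), and Pfkfb1, a regulator of glycolysis (-1.77 ± 0.29), were also lower.

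Immediate early genes, which respond first to a stimulus, had 14 of 20 tested members higher in IR edit than in Sham, and 15 adjusted over the list alone. Nr4a1, Fos, a subunit of the AP-1 transcription factor (2.70 ± 0.37), and the transcription factor Klf4 (0.78 ± 0.11) had the smallest p. The list's median was 0.83 (camera adjusted p = 2.95e-12, and adjusted p = 0.386 with an estimated correlation). Among cardiac stress genes 13 of 19 rose: Ankrd1 by 2.36 ± 0.30, Rcan1, an inhibitor of calcineurin that calcineurin itself induces, by 1.82 ± 0.28, and Myh7, the beta myosin heavy chain, by 2.82 ± 0.47. Adjusted over the list alone 16 passed (camera adjusted p = 6.54e-10, and adjusted p = 0.386 with an estimated correlation). Among collagens 15 of 29 rose, including the basement membrane chains Col4a1 (0.97 ± 0.17) and Col4a2 (0.90 ± 0.17) and Col16a1 (1.16 ± 0.25). The number that rose was 25 adjusted over the list alone (camera adjusted p = 1.26e-11, and adjusted p = 0.386 with an estimated correlation). Activated fibroblast and matricellular genes had 21 members higher and 1 lower of 43, with Thbs1 at 1.95 ± 0.37, Thbs4 at 1.76 ± 0.34 and Fbn1, which encodes fibrillin, at 1.34 ± 0.26. Adjusted over the list alone, 29 were higher and 1 lower (camera adjusted p = 1.06e-09, and adjusted p = 0.46 with an estimated correlation). Among fatty acid genes 10 of 35 fell, including the lipase Lpl (-0.47 ± 0.085) and the beta-oxidation proteins Echs1 (-0.41 ± 0.085) and Etfa (-0.48 ± 0.11). Adjusted over the list alone 23 fell (camera adjusted p = 2.24e-11, and adjusted p = 0.386 with an estimated correlation). In the TCA cycle list 3 of 20 fell: Pdhb and Dld, parts of the pyruvate dehydrogenase complex (-0.31 ± 0.077 and -0.35 ± 0.099), and Suclg2, a succinyl-CoA ligase subunit (-0.46 ± 0.12). There were 11 lower members adjusted over the list alone (camera adjusted p = 1.91e-06, and adjusted p = 0.46 with an estimated correlation).

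The circadian clock list also passed in IR edit against Sham, with 3 members higher and 9 lower of 17, or 4 and 9 adjusted over the list alone (median -0.54, adjusted p = 0.00927, and adjusted p = 0.386 with an estimated correlation). So did proliferation, with 2 of 22 higher, or 6 higher and 1 lower adjusted over the list alone (median 0.58, adjusted p = 0.000774, and adjusted p = 0.56 with an estimated correlation). The unfolded protein and integrated stress response had 7 higher and 1 lower of 24, or 8 and 1 adjusted over the list alone (median 0.15, adjusted p = 0.0127, and adjusted p = 0.46 with an estimated correlation). Respiratory chain genes (51 of 52 negative, median -0.19, adjusted p = 2.89e-09) and mitochondrially encoded genes (12 of 13 negative, median -0.26, adjusted p = 0.00274) had adjusted p = 0.46 and 0.499 with an estimated correlation. Neither list had a member called by edgeR over all genes or adjusted over the list alone. The IR edit hearts differed in the lists of injury and metabolism, with Thbs1 at 30.4, 70.7, 31.4 and 90.1 CPM, Col4a1 at 679, 767, 462 and 812 and Etfa at 438, 389, 537 and 368 in replicates 1 to 4.

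In edgeR's quasi-likelihood test 1257 genes passed in IR edit against Sham, 723 higher and 534 lower, and 330 of them changed at least 2-fold. The adjusted p was 9.11e-06 for Nr4a1 and 1.1e-05 for Dbp, and between 0.000132 and 0.0447 for the other named genes. The count was 2351 without IR edit replicate 3, 478 without replicate 2, 550 without replicate 4 and 642, 800 and 664 without Sham replicate 1, 2 or 3. It was 2205 without a filter and 246 in a fit of only the 2 groups, where 245 of the 1257 genes passed. The fits with a library left out kept all 4 groups. In them, 24 of 29 named genes passed whichever library was left out. The others were Ccl11, Etfa, Pdhb, Suclg2 and Dld, with largest adjusted p of 0.0679, 0.0609, 0.0842, 0.112 and 0.174. Each of these was lost without IR edit replicate 2, and all but Etfa without IR edit replicate 4. All but Ccl11 were lost without Sham replicate 3, Ccl11 and Dld without Sham replicate 1, Pdhb and Dld without Sham replicate 2, and Dld without IR edit replicate 1.

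The comparison of IR edit with IR virus asks what the editing system changed in injured hearts that all received a virus or an editing system. Nr4a1 rose from 3.38 ± 0.621 CPM in IR virus (SD, n = 3) to 36.7 ± 12.3 in IR edit (n = 4), a log2 fold change of 3.44 ± 0.27 (SE; adjusted p = 1.04e-05). Its relative Nr4a3 rose by 2.98 ± 0.41, Lpar3, a receptor for lysophosphatidic acid, by 3.13 ± 0.27, and Hspa1a, an inducible heat shock protein with a near-identical copy in the genome, by 2.92 ± 0.38. Mylk2 and Syndig1 rose by 2.89 ± 0.51 and 2.82 ± 0.51, to 2.77 ± 1.82 and 2.74 ± 1.70 CPM. Dbp fell by 2.82 ± 0.18 (adjusted p = 2.13e-06), from 41.8 ± 6.46 CPM to 5.94 ± 1.72, and the clock repressors Per3, Ciart and Per2 were lower at -1.89 ± 0.20, -1.81 ± 0.25 and -1.69 ± 0.36. Inmt, an indolamine methyltransferase, and Ucp3, a mitochondrial carrier of muscle, were lower too, at -1.78 ± 0.39 and -1.59 ± 0.26. The largest adjusted p among these genes was 0.0295.

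**Figure D2:**
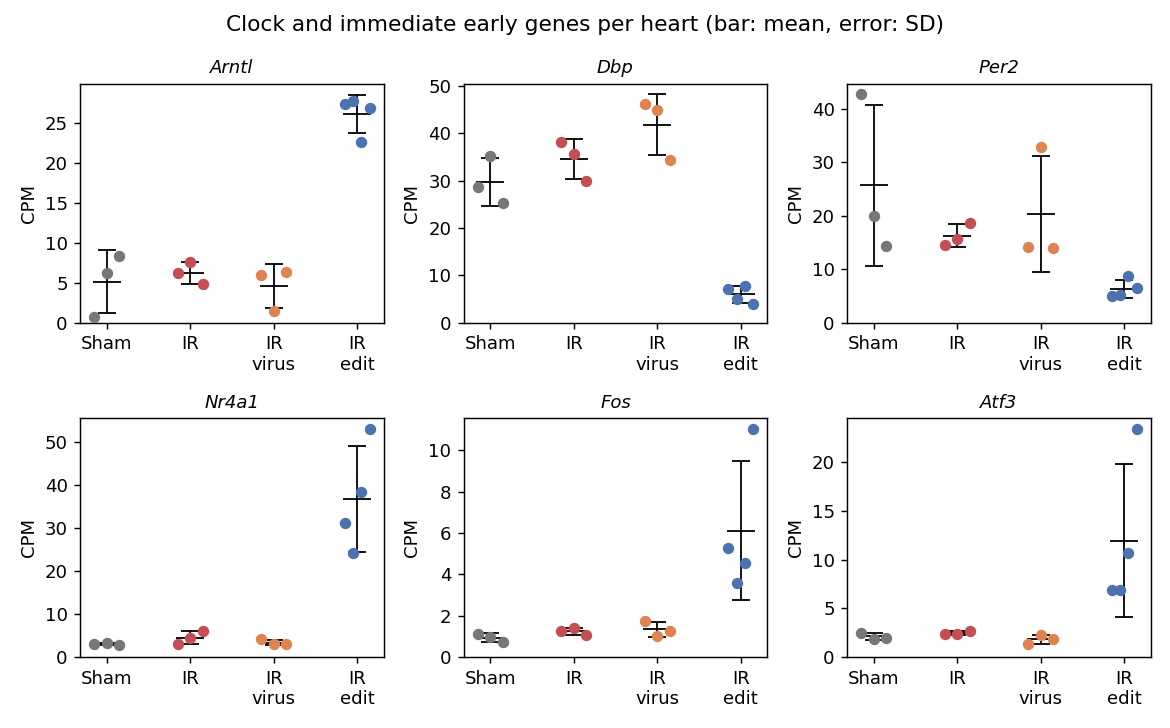
CPM of 6 genes on the vertical axes, with 1 point per heart in the 4 groups and the mean and SD as bars; Arntl, a core clock activator, was chosen after its values were seen. The 4 IR edit hearts sit between 22.6 and 27.7 CPM for Arntl, above the 8.33 CPM of the highest heart elsewhere, and between 4.01 and 7.66 CPM for Dbp.

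In the circadian clock list 12 of 17 members passed in IR edit against IR virus, 3 higher and 9 lower, and 4 and 10 adjusted over the list alone. Dbp, Per3 and Bhlhe41, a transcriptional repressor of the clock (-0.94 ± 0.11, adjusted p = 0.000231), were its members with the smallest p, and the list's median was -0.85 (camera adjusted p = 0.000574, and adjusted p = 0.309 with an estimated correlation). Arntl rose by 2.51 ± 0.48, named after its values were seen, from 4.57 ± 2.72 CPM in IR virus (n = 3) to 26.1 ± 2.38 in IR edit (n = 4). Every IR edit heart was above every heart of the other groups for Arntl and under every one of them for Dbp and Per2.

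Immediate early genes had 8 of 20 members higher and 0 lower in IR edit than in IR virus by edgeR over all genes, and 13 adjusted over the list alone. Nr4a1, Klf4 (0.95 ± 0.11, adjusted p = 0.000231) and Nr4a3 (adjusted p = 0.00165) had the smallest p, and the median was 0.79 (camera adjusted p = 2.83e-12, and adjusted p = 0.459 with an estimated correlation). In the unfolded protein and integrated stress response 2 of 24 rose, Atf3, a stress-induced transcription factor that is also on the immediate early list (2.70 ± 0.39), and Atf4, the main transcription factor of the integrated stress response (0.55 ± 0.12). Xbp1 did not pass (0.26 ± 0.082, adjusted p = 0.14). Adjusted over the list alone 4 members passed, and the list had a camera adjusted p of 0.0068 and adjusted p = 0.586 with an estimated correlation. Among cardiac stress genes Rcan1 alone of 19 rose (1.24 ± 0.27, adjusted p = 0.0283), while Ankrd1 (1.07 ± 0.28, adjusted p = 0.0697) and Ankrd23 (0.61 ± 0.26, adjusted p = 0.279) did not pass. Of the 19, 2 passed adjusted over the list alone, and the median was 0.48 (camera adjusted p = 0.0144, and adjusted p = 0.841 with an estimated correlation). The IR edit hearts differed within this list. Nppa was at 98.9, 304, 55.9 and 422 CPM in IR edit replicates 1 to 4, against 146 to 154 in IR virus. Rcan1 was at 124, 241, 90.9 and 249.5 CPM, against 66.4 to 81.2 in IR virus.

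Fatty acid genes had 33 of 35 members lower in IR edit than in IR virus, 2 of them past the threshold over all genes and also adjusted over the list alone. These were Cpt1a, which admits fatty acids to mitochondria (-0.57 ± 0.087, adjusted p = 0.00363), and Ucp3. Acot2, a mitochondrial thioesterase, did not pass (-0.43 ± 0.14, adjusted p = 0.163), and the list's median was -0.18 (camera adjusted p = 5.64e-06, and adjusted p = 0.78 with an estimated correlation). Atrial markers had 12 of 14 members lower, 2 past the threshold. These were Nr2f2, a transcription factor of atrial identity (-0.48 ± 0.083, adjusted p = 0.00837), and Dkk3 (-1.10 ± 0.27, just under the threshold). Sbk3 did not pass (-0.91 ± 0.25, adjusted p = 0.0845). Of the 14, 3 passed adjusted over the list alone, and the median was -0.54 (camera adjusted p = 0.000196, and adjusted p = 0.586 with an estimated correlation). Myl7, the atrial myosin light chain, shown after its values were seen, was at 8.87, 21.6, 5.69 and 3.92 CPM in the IR edit hearts, 22.3 to 31.7 in IR virus and 1.56 in Sham replicate 3. MHC and antigen presentation genes had 21 of 23 members lower (median -0.27, camera adjusted p = 0.000423), interferon-stimulated genes 23 of 30 (-0.18, 0.0068) and TCA cycle genes 19 of 20 (-0.08, 0.0431). These had adjusted p = 0.78, 0.841 and 0.841 with an estimated correlation, and 0 members called by edgeR over all genes or adjusted over the list alone.

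**Figure D3:**
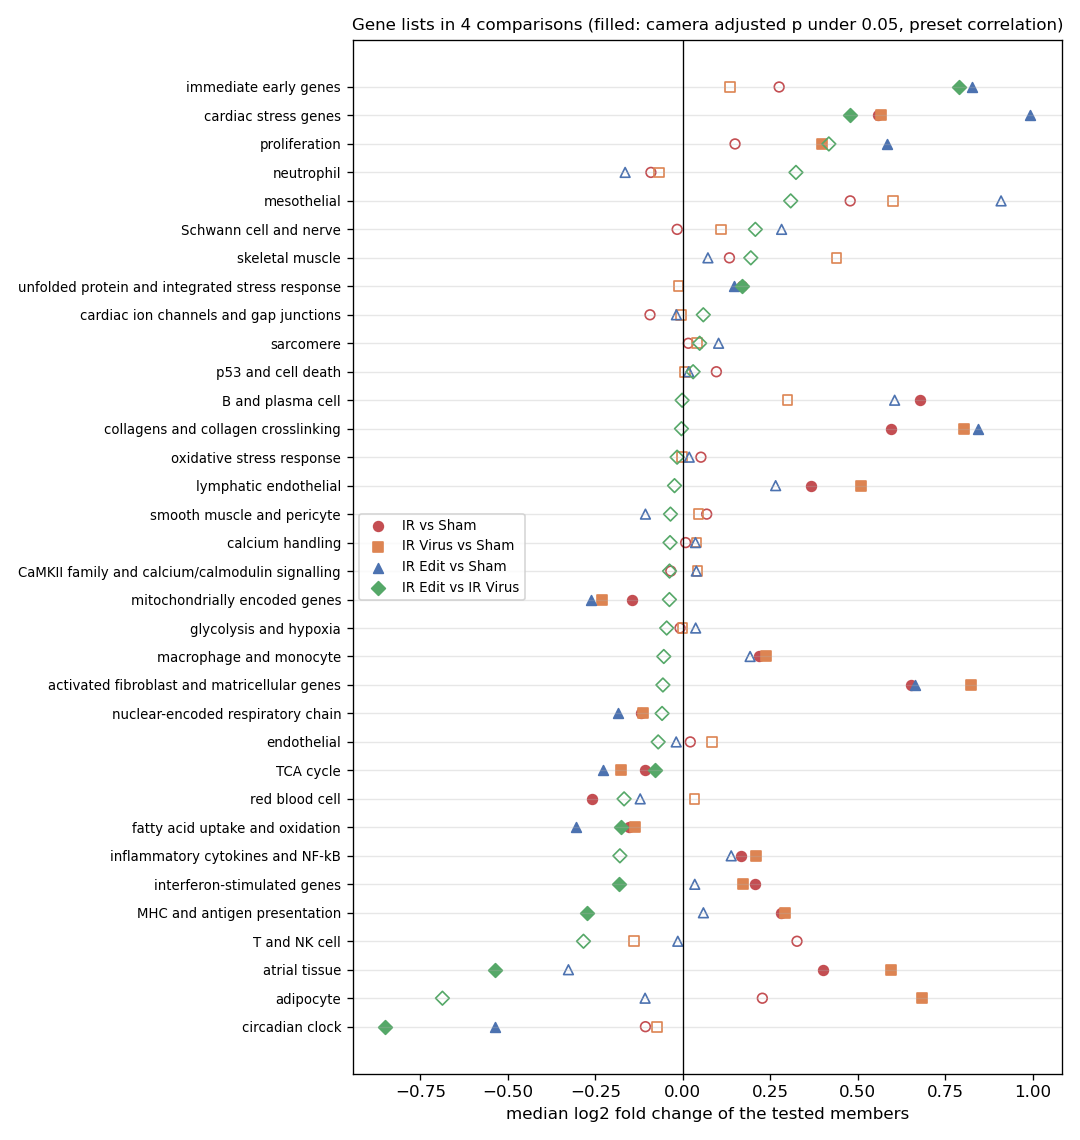
Median log2 fold change of the tested members (horizontal axis) of 34 gene lists (vertical axis) in 4 comparisons, with filled symbols where camera's adjusted p was under the threshold at the preset correlation. In IR edit against IR virus the immediate early list has a median of 0.79 and the clock list one of -0.85; no list passed with an estimated correlation.

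In edgeR's quasi-likelihood test 317 genes passed in IR edit against IR virus, 151 higher and 166 lower, with 2380 at an unadjusted p under 0.05. The count was 495 with DESeq2, 1018 without a filter, 96, 122 and 114 without IR virus replicate 1, 2 or 3, and 477, 146 and 177 without IR edit replicate 1, 2 or 4. Of 20 named genes 13 passed whichever library was left out. Dkk3 was lost whichever of the 7 libraries was left out (largest adjusted p 0.187). The others were Mylk2, Syndig1, Inmt, Per2, Atf4 and Rcan1, with largest adjusted p of 0.0614, 0.0615, 0.175, 0.145, 0.11 and 0.121. Of these 6, all but Per2 were lost without IR virus replicate 1, all but Mylk2 without replicate 2, and Mylk2, Syndig1, Atf4 and Rcan1 without replicate 3. Inmt, Per2, Atf4 and Rcan1 were lost without IR edit replicate 2, and Inmt, Per2 and Rcan1 without IR edit replicate 4.

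Whether genes changed by the injury moved back in IR edit hearts was measured across all 15690 genes. The log2 changes of IR against Sham and of IR edit against IR virus correlated at r = -0.0424 across genes, with an exact permutation p of 0.886 over the 35 splits of the 7 libraries (two-sided), which gave r from -0.373 to 0.445. Genes are not independent replicates. Spearman's rho was 0.000189, and r was 0.0023 without Sham replicate 3, 0.00078 without IR edit replicate 1 and 0.081 without IR edit replicate 3. The IR score, built on 100 genes higher and 100 lower in IR, was -1.53 ± 0.0976 in Sham (SD, n = 3) and 0.34 ± 0.234 in IR (n = 3). It was 0.32 ± 0.299 in IR virus (n = 3) and 0.42 ± 1.06 in IR edit (n = 4). The IR edit hearts scored -0.08, 1.04, -0.81 and 1.53, so the spread within this group exceeded the difference of 0.10 from IR virus (exact permutation p = 0.943). That difference turned negative without IR replicate 3 (-0.09), IR virus replicate 2 (-0.07), IR edit replicate 2 (-0.10) or IR edit replicate 4 (-0.26). Of the 100 genes higher in IR, 45 had a lower mean in IR edit than in IR virus, and of the 100 lower in IR, 30 had a higher one. The score contains Sham and IR libraries in its gene choice, so its Sham and IR values are not independent of that choice.

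**Figure D4:**
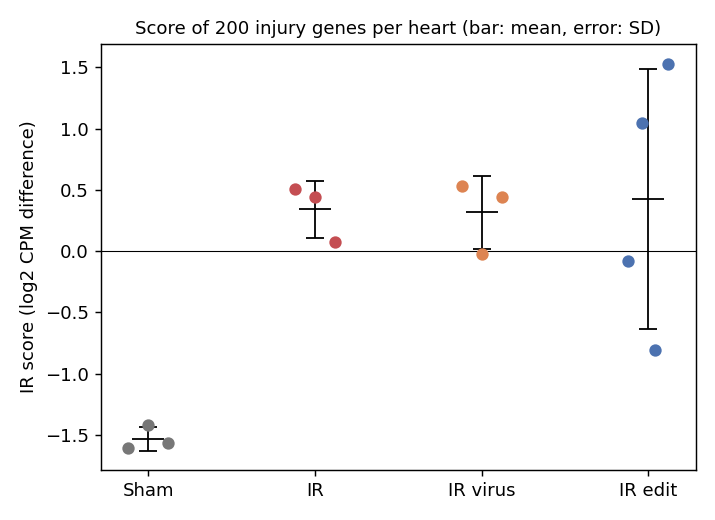
IR score on the vertical axis, the mean log2 CPM of 100 genes higher in IR minus that of 100 genes lower in IR, with 1 point per heart in the 4 groups and the mean and SD as bars. The 4 IR edit hearts run from -0.81 to 1.53, while the IR virus hearts run from -0.02 to 0.53.

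The comparison of IR edit with IR repeats the contrast against injured hearts without injection. Nr4a1 rose by 3.03 ± 0.26 (SE), Lpar3 by 2.77 ± 0.26 and Pnpla3, a lipid droplet protein, by 2.77 ± 0.22, to 7.41 ± 1.22 CPM (SD, n = 4) from 1.08 ± 0.177 (n = 3). Mylk2 and Syndig1 rose by 3.33 ± 0.54 and 2.92 ± 0.52. Dbp (-2.55 ± 0.18), Per3 (-1.71 ± 0.20), Ciart (-1.56 ± 0.26), Gpnmb, a glycoprotein of activated macrophages (-1.44 ± 0.28), and Ucp3 (-1.40 ± 0.26) were lower, with adjusted p up to 0.0187 among the 10 named genes. Immediate early genes had 8 of 20 members higher, or 14 adjusted over the list alone. Clock genes had 3 higher and 6 lower of 17, or 5 and 10 adjusted over the list alone. The counts over all genes and adjusted over the list alone were 2 and 2 lower of 35 fatty acid genes, 1 and 3 higher of 19 cardiac stress genes and 1 and 2 lower of 14 atrial markers.

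In edgeR's quasi-likelihood test 223 genes passed in IR edit against IR, 123 higher and 100 lower. Of these, 95 were also higher and 78 also lower against IR virus, where independent calls would share 1.18 and 1.06. Opposite calls numbered 0, and the simulations without changed genes shared 0. Since the same IR edit hearts serve both contrasts, they were divided 2 and 2 in 6 ways, which left 34 to 76 shared calls in the same direction. The changes of the divided groups correlated across genes at r from 0.285 to 0.525, genes not being independent replicates. The count of 223 was 427 with DESeq2, 1021 without a filter, 67 and 59 without IR replicate 1 or 2 and 129, 489 and 127 without IR edit replicate 2, 3 or 4. Mylk2, Syndig1, Gpnmb and Ucp3 were lost without IR replicate 2, with largest adjusted p of 0.0501, 0.0791, 0.123 and 0.0835, the last 3 also without IR replicate 1.

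Camera placed 10 lists past the threshold in IR edit against IR. On the positive side were immediate early (median 0.82, adjusted p = 2.69e-13), proliferation (0.59, 0.0013), cardiac stress (0.47, 0.0013) and sarcomere genes (0.14, 0.00918). On the negative side were fatty acid (median -0.17, adjusted p = 6.66e-06), atrial (-0.45, 0.0013) and MHC genes (-0.19, 0.0013). Interferon-stimulated (median -0.17, adjusted p = 0.0013), clock (-0.64, 0.00435) and TCA cycle genes (-0.09, 0.01) were on that side too. Over all genes 0 members of the MHC and sarcomere lists passed by edgeR, with 2 lower and 1 higher adjusted over the list alone. The proliferation, interferon-stimulated and TCA cycle lists had 0 members called over all genes and 0 adjusted over the list alone. With an estimated correlation 0 lists passed, the smallest adjusted p was 0.385 and 4 had an unadjusted p under 0.05.

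The comparison of IR virus with IR asks what the control virus changed in injured hearts, and no gene passed edgeR's quasi-likelihood test. Among the 5 named genes with the smallest p were Itga3, an integrin (0.55 ± 0.13), the zinc finger gene Zkscan17 (0.41 ± 0.11) and Trappc9, a vesicle transport protein (0.40 ± 0.11). The others were Ppp1r16a, a regulator of protein phosphatase (0.41 ± 0.11), and Myh14, a non-muscle myosin heavy chain (0.46 ± 0.13), and all 5 had an adjusted p of 0.962. The count of 0 compares with 603 genes at an unadjusted p under 0.05, 0 with DESeq2, 37 without a filter and 1 without IR replicate 3. Camera placed proliferation genes (21 of 22 members positive, median 0.25, adjusted p = 0.0497) and red blood cell genes (8 of 8, median 0.34, adjusted p = 0.0497) past the threshold, and both had adjusted p = 0.969 with an estimated correlation. The count of lists was 1 without IR replicate 2, and 0 without IR replicate 3 or IR virus replicate 3.

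Of the 34 lists tested, 13 did not pass in any comparison. For heart muscle these were CaMKII and calcium/calmodulin signalling (smallest camera adjusted p of the 6 comparisons 0.611), calcium handling (0.408) and cardiac ion channels and gap junctions (0.126). For other cell types and tissues they were smooth muscle and pericyte (0.271), endothelial (0.215), neutrophil (0.432), T and NK cell (0.0736), skeletal muscle (0.16), mesothelial (0.204) and Schwann cell and nerve genes (0.0627). The remaining ones were glycolysis and hypoxia (0.377), oxidative stress response (0.214) and p53 and cell death genes (0.195). The set test looks for a shift in 1 direction, so these lists can still hold called members. In IR edit against Sham, ion channel genes had 4 higher and 7 lower of 27 by edgeR over all genes. Adjusted over the list alone they had 7 and 7. T and NK cell genes had 0 higher and 2 lower of 6, or 1 and 2 adjusted over the list alone. Of all 15690 genes, 1257 passed in that comparison. Cartilage and bone markers, with 4 tested members, were too few for the set test; Runx2, a bone transcription factor, was their member with the smallest p in IR edit against Sham (1.01 ± 0.28, adjusted p = 0.0386). In all 62 list results past the threshold the median, the mean and the test had the same sign, and in 36 of the 204 list results tested they did not.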

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

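The tests on scaling, on 1 or 2 hearts and on atrial tissue were chosen only after the results they measure had been seen, while the tests on the daily cycle, on heat shock genes and on regrouped hearts were chosen before.

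Among the 59 values tested in the 4 IR edit hearts, 2 had 1 heart far from the others, and chance gives about 1 in 20, or 3 here. Lpar3 was at 5.23 CPM in IR edit replicate 1 against 3.83 to 3.96 in the other hearts, a gap of 0.903 of the group's range. Zkscan17 was at 11.4 CPM in IR edit replicate 3 against 12.4 to 12.5 in the others, a gap of 0.89 of the range.

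Regrouping the hearts of each comparison showed how often other splits gave as many genes as the real one. For the 317 genes of IR edit against IR virus, 1 of 35 splits, the real one, gave as many. The highest of the others gave 126. This argues against chance as the source of the count but does not exclude it. A share of 1 in 35 is the smallest these splits can give, and it was not corrected for the other counts regrouped. For the count of 1257 genes in IR edit against Sham the splits do not argue against chance. There 2 of 35 splits gave as many, and the other one, with IR edit replicate 3 placed among the Sham hearts, gave 2212. For the count of 223 genes in IR edit against IR they do not either: 2 of 35 splits gave as many, and placing IR edit replicate 3 among the IR hearts gave 334. That split called more genes than the real one both times, which points to a structure within the IR edit group. The 223 are left open only as a count, since separate pairs of IR edit hearts, 1 pair against IR virus and 1 against IR, shared 34 to 76 calls in the same direction. The 10 splits of 3 against 3 hearts are too few for a share under 0.05. There the real and highest other counts were 2 and 0 for IR against Sham (1 of 10 splits as large), 2 and 0 for IR virus against Sham (1 of 10) and 0 and 0 for IR virus against IR (10 of 10).

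For the number of gene lists past the threshold chance cannot be excluded in the contrasts of IR edit hearts. The splits counted lists and did not test any single list, so the lists are left open here only as a count. In IR edit against Sham, 16 of 35 splits gave at least the real 11 lists, with up to 16 in another split. In IR edit against IR virus, 21 of 35 splits gave at least 9, with up to 16. In IR edit against IR, 17 of 35 splits gave at least 10, with up to 15. The 10 splits of the other comparisons are again too few: the real and highest other counts were 15 and 10 for IR against Sham (1 of 10 as large), 15 and 11 for IR virus against Sham (1 of 10) and 2 and 6 for IR virus against IR (8 of 10).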

How the results depend on the processing

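The fit of the 9 libraries outside IR edit was added after the data had been seen. Counts of genes past the threshold kept within 1.5 times the reported value with DESeq2's size factors and with the 1 CPM filter in all 6 comparisons. Without a filter they were 598, 863 and 2205 for IR, IR virus and IR edit against Sham, and 1018, 1021 and 37 for IR edit against IR virus, IR edit against IR and IR virus against IR. In the same order, the replicate number as a block gave 5, 174 and 590, and then 159 and 122, with 0 for IR virus against IR. A pairing of the hearts by these numbers was not established, and the checks made do not rule it out. IR edit replicate 4 has no heart of its number in the other groups, so the block takes it out of the comparisons. DESeq2's Wald test gave 48 and 191 for the first 2 comparisons, 495 for IR edit against IR virus and 427 for IR edit against IR. A robust dispersion left 1 gene each in IR and IR virus against Sham. A fit of only the 2 groups gave 115, 203 and 246 against Sham. The 9 libraries outside IR edit gave 156 and 313 for IR and IR virus. The low counts of 2 genes each in IR and IR virus against Sham thus depended on having the IR edit hearts in the fit. Cilp, Sfrp2, Col8a2 and Ankrd1 had log2 fold changes of 2.895, 2.547, 2.133 and 1.484 for IR against Sham in the fit of those 2 groups. In the fit of all 13 libraries they had 2.899, 2.551, 2.137 and 1.488. For these genes the p differed between the fits and the size of the change hardly did. How the IR edit hearts lowered the counts was not tested. Leaving out 1 library gave 0 to 5, 0 to 7 and 478 to 2351 genes against Sham, 96 to 477 for IR edit against IR virus, 59 to 489 for IR edit against IR and 0 to 1 for IR virus against IR. Fewer hearts were then fitted, and the cause of the higher counts was not tested.

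With an estimated correlation 0 lists passed by camera in all 6 comparisons, with 2, 1, 3, 2, 4 and 0 at an unadjusted p under 0.05. The 2 lists of IR virus against IR became 1 with the block and 0 to 3 when 1 library was left out. The correlation with the injury change was 0.000189 by Spearman and -0.1485 to 0.0812 when 1 library was left out. The IR score difference was -0.264 to 0.514 when 1 library was left out. With the block it was -0.264, the same value as without IR edit replicate 4, which the block leaves out. Camk2d turned direction in IR against Sham without Sham replicates 2 and 3 (0.0069 and 0.0233, range -0.209 to 0.0233). It also turned in IR edit against IR virus without IR virus replicate 2 and IR edit replicate 3 (-0.0224 and -0.011, range -0.0224 to 0.096), and the cause was not tested. Of 1162 alternatives for the 83 single-gene results, 1032 stayed on the same side of the threshold, 96 lost the call, 30 gained one and 4 turned direction. Depth limits genes with few reads, such as Mylk2 and Syndig1 in Sham.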

Other observations

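The tests on scaling, on 1 or 2 hearts and on atrial tissue, and the genes named in the next paragraph, were chosen only after the results had been seen.

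In edgeR's quasi-likelihood test, the ion channel genes Hcn4 (log2 fold change 0.79 ± 0.17 SE, adjusted p = 0.0266) and Kcna5 (1.14 ± 0.20, adjusted p = 0.0096) were higher in IR edit than in IR virus. Cdkn1a, an inhibitor of the cell cycle, rose by 1.97 ± 0.21 to 27.3 ± 8.83 CPM (SD, n = 4; adjusted p = 0.000122). Vegfa, a growth factor of vessels, rose by 0.33 ± 0.074 (adjusted p = 0.0307). The matrix genes Thbs2 (-0.98 ± 0.15, adjusted p = 0.00439) and Col11a1 (-1.77 ± 0.42, adjusted p = 0.0411) and the monocyte receptor Ccr2 (-1.22 ± 0.25, adjusted p = 0.0211) were lower. Of 88 genes higher in IR than in Sham in a fit of those 6 libraries alone, 55 were higher and 33 lower in IR edit than in IR virus. Gpnmb (-1.54 ± 0.28), Ptn, a secreted growth factor (-1.26 ± 0.24), Fmod, a small matrix proteoglycan (-1.52 ± 0.32), and Col6a5, with few reads, passed as lower, where independent calls would give 0.931. Rcan1 (1.24 ± 0.27) and Masp1, a complement protease (1.03 ± 0.23), passed as higher, where 0.847 would be shared. Of 27 genes lower in IR, 0 passed by edgeR in IR edit against IR virus, 21 of them being lower and 6 higher.

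The clock genes of IR edit hearts differed from those of IR virus hearts, with 3 members higher and 9 lower. Scaling of the libraries is argued against as the whole cause, since a common factor moves all members alike, while the log2 fold changes of all 17 tested members had an SD of 1.37 and their SE was at most 0.484. A harvest at another time of day may be behind it: 100 genes outside the lists that followed the clock among the other 9 hearts, less 100 that opposed it, differed by 0.273 in the direction this needs, with an exact permutation p of 0.31. With the same genes the difference was 0.00615 without IR virus replicate 2, which with Sham replicate 1 stood apart among the 9 (Arntl at 1.43 and 0.755 CPM against 4.85 to 8.33), and 0.23 to 0.424 without any other heart. The IR virus hearts were among the 9 used to choose these genes, so their spread in this measure is not independent of the choice. The result leaves the question open, and the labels give no hour of harvest. An hour that differed between the groups cannot be told apart from an effect of the editing system on clock genes.

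The immediate early genes were higher in IR edit than in IR virus, with 8 of 20 members called. A response of only 1 or 2 stressed hearts is argued against, since in the mean log2 CPM of all 20 tested members the third highest IR edit heart lay 0.648 above the highest IR virus heart, and the lowest 0.505 above it (SD of the IR virus hearts 0.0861). Heat or handling stress of the tissue may be behind it: 12 heat shock genes outside the lists had a median log2 fold change of 0.273. They ran from 0.0045 ± 0.13 (SE, Hspd1) to 0.83 ± 0.25 (Hsp90aa1), so 12 of 12 were positive, if only barely for Hspd1. Their mean differed with an exact permutation p of 0.029, the smallest possible. By edgeR 0 of the 12 passed, while Hspa1a, Hspa1b and Dnajb1, heat shock genes outside that set, did. An effect of the editing system stays open and was not tested apart from handling. The IR edit hearts also stood apart in clock genes, and an hour of harvest was not tested apart from handling either.

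The cardiac stress genes were higher in IR edit than in Sham, with 13 of 19 members called, and Nppa, also an atrial marker, rose by 3.38 on the log2 scale. More atrial tissue in the IR edit libraries is argued against as the source, since the other 13 atrial markers had a median of -0.328 (SD 0.998). The IR edit hearts differed from each other in these genes, with Myh7 at 523, 1950, 500 and 2000 CPM. Differences in injury between hearts could account for this spread, and the labels hold no measure of injury that would test it. An effect of the editing system on these genes was not tested apart from the injury, and no gene list separates the alternatives.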
